A study of Mus musculus with 4 samples.

How the data were processed

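Gene expression was measured on Affymetrix Mouse Gene ST arrays in sorted dermal papilla cells of 2 Sox2 heterozygous and 2 Sox2 conditional knockout samples from mice at postnatal day 5. Per the labels' protocols, total RNA was isolated with a microprep kit, amplified with a whole-transcript kit and labelled with biotin; amplification of small amounts of RNA adds variation between samples that the arrays cannot separate from variation between animals. The deposited values were made by the authors with RMA, per the submitters' processing notes, and RMA gives values on the log2 scale; the base of the logarithm is not stated in the deposited table and log2 was assumed for every fold given here. The software version, the genome build and the centring step are not given in the sources used here. In the deposited table the median of the 4 arrays was 0 in all 28853 probe sets, within 1e-06. Only differences between arrays are therefore left, and no expression level, detection or background can be read from them. The medians of the arrays were -0.00366 and 0.000162 in Het and -0.000575 and 0.0043 in cKO, so the arrays were level with each other.

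The centring changed the planned fit. The plan had been to leave out probe sets below the 40th percentile of mean expression and to represent each gene by its brightest probe set; neither can be done without an expression level. All probe sets were therefore tested, and each gene was given the mean over all probe sets that name that gene alone, which had been planned as an alternative. Dim probe sets thus stay among those tested, which adds to the number of tests and places quiet probe sets in the estimate of the spread.

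Probe sets were named through the platform annotation. Of the probe sets, 21789 named 1 gene, 1621 named several and were given no name, and 5443 had no listed gene. A gene table of the assembly GRCm38.p6 was used to update symbols, which changed 0 of them, and to find which genes neighbour each other; no coordinates are given. This left 19938 genes, 999 of them with more than 1 probe set.

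Groups were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with the default prior, group as the only term, moderated test, two-sided), with Benjamini-Hochberg adjustment over the 28853 probe sets or 19938 genes and a threshold of 0.05. The fit had 2 residual degrees of freedom, and the prior added 1.42 for probe sets and 1.52 for genes. Standard errors are those of this fit. Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the 31 lists with at least 5 measured genes. The 20 gene lists and 12 cell type lists, the tests, the thresholds and the rule for naming genes were chosen before the data were examined. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

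Genes were named by this rule: Sox2; up to 15 genes per direction that passed over all genes with separated groups; where fewer passed, genes with a difference of at least 2-fold, an unadjusted p under 0.01 and separated groups, the largest differences first; the 4 largest differences of each list and every gene that passed adjusted over the list alone; and Sostdc1, Bmp4, Bmp6, Nog, Id1, Id2, Id3, Alpl, Corin, Lef1, Vcan, Prom1, Crabp1 and Itga9 in any case. It gave 128 genes, of which the report describes a part. Kdm5c, Kdm6a and Eif2s3x were chosen after Xist was seen and before their own values were. Cwc22, Usp9y and the other genes of the closing observations outside this rule were chosen after their values were seen.

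The fit was tested on simulated data in which 100 genes were changed by a log2 value of 1 and 100 by 2, for the comparison of cKO with Het over 19938 genes. It called 59 of the 100 genes changed by 1 and 88 of the 100 changed by 2, with 7 false calls. Over 28853 probe sets it called 64 and 85 of 100, with 7 false calls. All changes were simulated at once, which eases the Benjamini-Hochberg threshold for each, so these rates do not carry over to data with fewer changes. In the real data Sox2, at -1.81 ± 0.06, had an adjusted p of 0.345 (limma). A count of 0 calls therefore does not show that changes of this size are absent. Of the probe sets left unchanged in the simulation, 1668 had an unadjusted p under 0.05. A list shifted by -0.3 was called in 20 of 20 repeats and 1 of 600 tests of other lists was called. Genes varied independently in these list simulations, whereas the estimated correlation in the arrays ran from -0.193 (sex-linked genes) to 0.673 (keratinocyte markers). It was 0.278 for the immediate early genes and 0.0402 for the axon guidance genes. The rate of false list calls in these arrays is therefore not known. The shift was also larger than the median difference of each called list except the sex-linked genes.

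Alternatives were arrays centred on their medians, a robust prior, the replicate number as a block, an unmoderated statistic, each array left out in turn, a 1.5-fold threshold, an adjusted p of 0.1, camera with an estimated correlation and fry. Added after seeing the data were a filter that keeps the probe sets with the larger SD, genes with 1 probe set only, and list tests without the sex-linked genes. A stricter filter on dim probe sets, a prior with a trend on expression, a further quantile normalization and cyclic loess had been planned and were not run, since they rest on expression levels.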

Results

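The series profiled dermal papilla cells, the mesenchymal cells at the base of the hair follicle, from mouse skin at postnatal day 5. Cells carrying a Sox2-driven green fluorescent protein and the surface marker integrin alpha 9 were sorted from animals heterozygous for Sox2 (Het) and from animals with a conditional knockout of Sox2 (cKO), a transcription factor of the SOX family. Each group had 2 arrays, labelled as biological replicates 1 and 2, and each of the 4 arrays gave a value for 28853 probe sets. The values held differences between arrays and no expression level, because every probe set had been centred on its median over the 4 arrays. The comparison addresses how loss of Sox2 alters the expression profile of the dermal papilla. The labels do not say whether the replicates came from separate animals, litters or pools, so p-values measure the spread between these samples. The number of arrays limits the precision of every value. The SD of the differences over all probe sets was 0.19 between the Het arrays and 0.21 between the cKO arrays. Over the 4 pairs that cross the groups it was 0.26 for Het replicate 1 with cKO replicate 2. It was 0.19 for Het replicate 1 with cKO replicate 1, and 0.18 and 0.20 for Het replicate 2 with cKO replicates 1 and 2. By this measure arrays of different groups were thus not generally further apart than the cKO arrays.

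Sox2 itself was lower in both cKO arrays. Its only probe set stood at 0.96 and 0.87 in Het replicates 1 and 2 and at -0.87 and -0.94 in cKO replicates 1 and 2, on the log2 scale relative to the median of the 4 arrays. The difference, cKO minus Het, was -1.81 ± 0.06 (SE, n = 2 arrays per group), or 3.51-fold lower. The SD within a group was 0.06 in Het and 0.05 in cKO. The difference did not pass limma's test adjusted over all genes (adjusted p = 0.345), and it passed adjusted over the list alone in the dermal papilla signature (adjusted p = 7.3e-04), the SOX family (adjusted p = 3.1e-04) and the Merkel cell markers (adjusted p = 2.2e-04, limma). These list values adjust the same unadjusted p-value over 42, 18 and 13 genes and are not adjusted over the lists, so they are not separate tests. The position of the Sox2 probe set relative to the deleted part of the gene was not examined here, so it is open how far its value checks the labels.

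A rule on size and p-value, which takes differences of at least 2-fold with separated groups and an unadjusted p under 0.01, named 10 genes lower in cKO, Sox2 among them, and 0 genes higher. Xist and Ndnf, described below, were higher in cKO by more than 2-fold with separated groups and did not meet the limit on p. Fam210b, which encodes a mitochondrial protein, differed by -1.99 ± 0.22, a 3.97-fold lower value. Slc26a7, an anion transporter gene, differed by -1.79 ± 0.32. Map1b, a microtubule-associated protein gene best known from growing axons, differed by -1.53 ± 0.12, and Snap91, which encodes a clathrin assembly protein of synapses, by -1.13 ± 0.14. Luzp2 differed by -1.45 ± 0.28 and Sparcl1, a matricellular protein gene related to Sparc, by -1.14 ± 0.15. Egr2, an immediate early transcription factor gene that also directs myelination in Schwann cells, differed by -1.35 ± 0.23. Vps36, a subunit gene of the endosomal sorting complex, differed by -1.07 ± 0.20. The tenth gene, the Y-linked Eif2s3y, is described with the sex-linked genes.

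**Figure D1:**
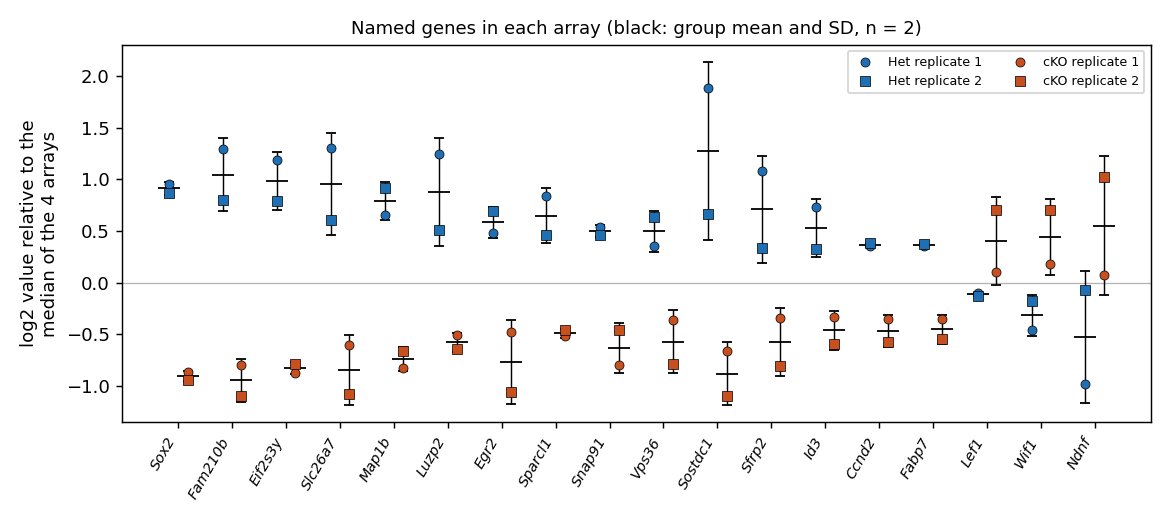
Values of 18 genes in each of the 4 arrays, on a log2 scale relative to the median of the 4 arrays, with Het in blue, cKO in orange, circles for replicate 1, squares for replicate 2, and black lines for the group mean and SD (n = 2). The arrays of Sox2 lie at 0.96 and 0.87 in Het and at -0.87 and -0.94 in cKO, whereas those of Sostdc1 range from 0.66 to 1.88 within Het.

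Over all probe sets, 0 of 28853 passed limma's test at an adjusted p of 0.05, the smallest adjusted p being 0.607. At an unadjusted p under 0.05 there were 1638 probe sets, 585 higher and 1053 lower in cKO. If chance spread p-values evenly it would give 1443, and this fit gave 1668 among the unchanged probe sets of the simulation. That simulation drew probe sets independently, each with its own residual SD estimated on 2 degrees of freedom, so 1668 is not a firm baseline. The split by replicate number gave 2227 and the remaining split of the 4 arrays into pairs 819. The 1638 lie between these counts and are not read as an excess over chance. The unmoderated statistic also called 0 probe sets, with 1462 at an unadjusted p under 0.05. Of 19938 genes 0 passed and 1053 lay under an unadjusted p of 0.05. By size, 42 probe sets differed at least 2-fold with groups that did not overlap, 14 of them higher and 28 lower in cKO; chance separates the groups in 33.3% of probe sets. The same rule gave 37 probe sets when the arrays were split by replicate number, and 13 for the remaining split of the 4 arrays into pairs. Of the 14 higher probe sets, 7 belonged to Cwc22, a splicing factor gene with 8 probe sets, so they are not 7 separate genes. The mean difference over its 8 probe sets was 0.95 ± 0.21, under 2-fold. At the gene level, 26 genes met the rule, 3 higher and 23 lower, against 17 and 0 genes for the other splits. Left out in turn, Het replicate 2 and cKO replicate 1 moved the probe set count most, to 85 and 124, where 3 arrays separate by chance in 66.7% of probe sets. The balance of directions also depended on single arrays: without cKO replicate 2 there were 33 probe sets higher and 19 lower, and without Het replicate 1 there were 30 higher and 32 lower. With only the probe sets of larger SD over all 4 arrays, a filter chosen after the data were seen, limma called 20 probe sets, 1 higher and 19 lower, with Sox2, Sostdc1, Fam210b, Slc26a7 and Map1b among them; that filter raised the prior degrees of freedom from 1.42 to 10.1.

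Genes of the BMP pathway, a signalling route between the papilla and the hair matrix above it, went both ways. Sostdc1, a secreted inhibitor of BMP and WNT signalling, had the largest difference of the lower genes named here at -2.15 ± 0.49, or 4.44-fold lower, and stood at 1.88 and 0.66 in the Het arrays against -0.66 and -1.10 in the cKO arrays. It did not pass over all genes (adjusted p = 0.934, limma). Id3 and Id1, transcriptional regulators induced by BMP signals, had log2 differences of -0.99 ± 0.18 and -0.32 ± 0.11, with separated groups, while Id2 was at -0.04 ± 0.13 with overlapping groups. Fst, which encodes the activin and BMP binding protein follistatin, was at 0.42 ± 0.11 and the ligand gene Bmp6 at 0.39 ± 0.15, both higher in each cKO array than in each Het array. With 1 array left out, Bmp6 shrank to 0.20 (without Het replicate 1) and Id1 to -0.21 (without cKO replicate 1). Bmp4 differed by 0.16 ± 0.15 and the antagonist gene Nog by -0.04 ± 0.04, both with overlapping groups. None of the BMP antagonists, with 10 of 20 genes higher and 10 lower, passed adjusted over the list alone or over all genes. The BMP ligands and receptors had 17 of 27 genes higher, and the BMP response genes had 7 of 16 higher. No BMP list was called by camera, with adjusted p-values of 0.979, 0.769 and 0.979 in that order.

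WNT genes were likewise divided. Among secreted inhibitors of the pathway, Sfrp2 differed by -1.28 ± 0.33 and Wif1 by 0.75 ± 0.22. The R-spondin gene Rspo3, whose product amplifies WNT signals, differed by -0.66 ± 0.13, and Rspo2 by -0.18 ± 0.06. Lef1, a nuclear partner of beta-catenin, differed by 0.51 ± 0.23, standing at 0.70 in cKO replicate 2 and at 0.10 in cKO replicate 1. Without cKO replicate 2, Lef1 shrank to 0.21 and Wif1 to 0.49. The WNT ligands and R-spondins had 11 of 20 genes higher, the secreted WNT inhibitors 9 of 17 and the beta-catenin targets 11 of 20, and camera called none of these lists (adjusted p = 0.979 for each). No WNT gene passed adjusted over the list alone.

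The dermal papilla signature, a list of 42 measured genes fixed for this tissue, was divided, with 21 genes higher and 21 lower in cKO and an adjusted p of 0.979 by camera. Sox2 was the 1 gene of the list that passed adjusted over the list alone, and 0 passed over all genes. Ndnf, a secreted factor gene, was higher at 1.08 ± 0.50, and at 0.62 without Het replicate 1 and 0.60 without cKO replicate 2. The matrix proteoglycan gene Vcan was lower at -0.77 ± 0.26, and Alpl, the alkaline phosphatase gene used to mark the papilla, was lower at -0.43 ± 0.08. Sox18, another SOX gene of the papilla, differed by 0.40 ± 0.15, and by 0.23 without cKO replicate 1. The surface protease gene Corin, at 0.15 ± 0.32, and Prom1, at -0.07 ± 0.13, had overlapping groups, as did Crabp1 at -0.32 ± 0.28. Itga9, which encodes the integrin used in the sort, differed by -0.14 ± 0.14 with overlapping groups. The list's median, 0.02, and its mean, -0.04, differed in sign.

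The axon guidance and adhesion genes were lower in cKO as a list. Of 35 measured genes 28 were lower, 14 of them with separated groups, and the median difference was -0.08 (camera, adjusted p = 3.0e-04). With an estimated correlation the call was lost (adjusted p = 0.853). Unc5c, a netrin receptor gene, differed by -0.77 ± 0.18, the guidance ligand genes Slit2 and Slit3 by -0.75 ± 0.33 and -0.41 ± 0.16, and the N-cadherin gene Cdh2 by -0.55 ± 0.17. None of the 35 genes passed adjusted over the list alone. The call with the preset correlation held without any single array, the adjusted p lying between 2.3e-05 and 0.0343, while the median moved to -0.17 without Het replicate 2. Without Het replicate 1, the difference of Slit2 shrank to -0.35 and that of Slit3 to -0.25.

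Extracellular matrix and basement membrane genes were lower in 32 of 47 cases, with a median difference of -0.10 (camera, adjusted p = 0.00114; adjusted p = 0.853 with an estimated correlation). Col15a1, a basement membrane collagen gene, differed by -0.82 ± 0.37 and Lum, the gene of the proteoglycan lumican, by -0.54 ± 0.12. Without cKO replicate 2 the list had a median of -0.05 (adjusted p = 0.0805) and Col15a1 a difference of -0.39, and without cKO replicate 1 the median was -0.16. The dermal fibroblast markers, a list of cells next to the papilla, were lower in 14 of 16 cases with a median of -0.23 (adjusted p = 0.0285; adjusted p = 0.853 with an estimated correlation). Of these markers 6 are also on the matrix list, among them Col1a1 at -0.31 ± 0.10 and Col1a2 at -0.37 ± 0.21, and the 10 others had a median of -0.08. The fibroblast call was lost without Het replicate 2 (median -0.17, adjusted p = 0.256), without cKO replicate 1 (median -0.23, adjusted p = 0.0688) and without cKO replicate 2 (median -0.12, adjusted p = 0.225). Col1a1 shrank to -0.18 without Het replicate 2 and Col1a2 to -0.11 without cKO replicate 2. No gene of either list passed adjusted over the list alone.

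Hypoxia and glycolysis genes were lower in 16 of 22 cases, with a median of -0.10 (camera, adjusted p = 0.00679; adjusted p = 0.985 with an estimated correlation). The glycolytic genes Ldha, Aldoa and Tpi1 differed by -0.63 ± 0.13, -0.50 ± 0.25 and -0.48 ± 0.22, and Vegfa, the angiogenic growth factor gene, by -0.39 ± 0.12, each with separated groups. The call was lost without Het replicate 2 (median -0.09, adjusted p = 0.0896) and without cKO replicate 2 (median -0.07, adjusted p = 0.225), where Aldoa shrank to -0.25 and Tpi1 to -0.24. Without cKO replicate 1 the median was -0.17. Immediate early and dissociation stress genes, which respond quickly to stimuli and tissue handling, were lower in 23 of 30 cases with a median of -0.14 (adjusted p = 0.0108; adjusted p = 0.985 with an estimated correlation). Ier3 differed by -0.79 ± 0.11 and Egr1 by -0.42 ± 0.18. This call was lost without Het replicate 2 (median -0.04, adjusted p = 0.341), and without cKO replicate 1 the median turned to 0.01 (adjusted p = 0.994) and Egr1 shrank to -0.19. Without cKO replicate 2 the median was -0.34. The immediate early list was also called when the arrays were split by replicate number. No gene of these lists passed adjusted over the list alone.

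**Figure D2:**
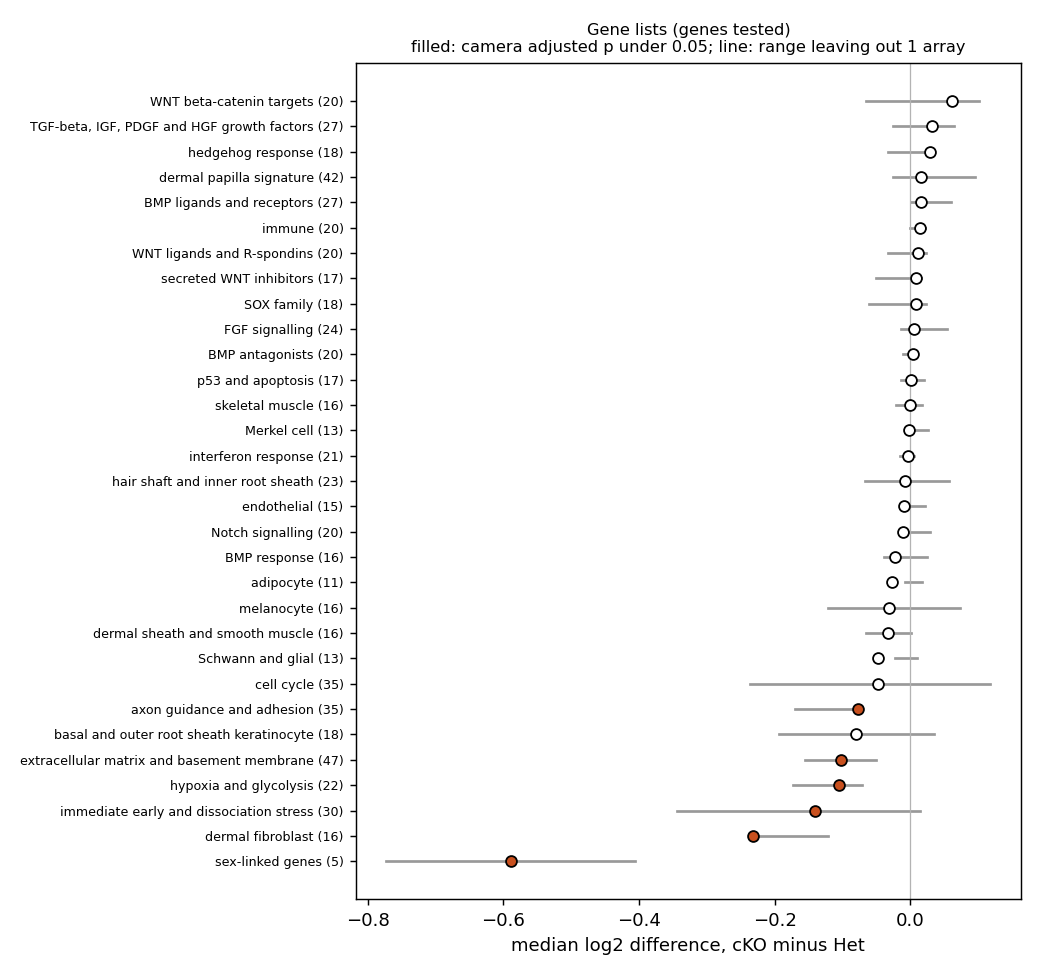
Median log2 difference, cKO minus Het, of the genes on each of 31 lists (genes tested in parentheses), with filled points for the 6 lists called by camera with the preset correlation and grey lines for the range of the median when 1 array is left out. The called lists lie at -0.08 or lower, and the line of the immediate early genes crosses 0.

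Of the 31 lists tested, camera with the preset correlation called 6, each of them lower in cKO, while 0 were called with an estimated correlation and 0 by fry in one direction. Fry's test for changes in either direction called 4 lists: the dermal papilla signature, the SOX family, the Merkel cell markers, all of which hold Sox2, and the BMP response. The other splits of the arrays called 4 lists each with the preset correlation. Among lists that were not called, the hedgehog response had 10 of 18 genes higher; its member Ccnd2, a cyclin gene, was lower at -0.83 ± 0.09 and passed adjusted over the list alone (adjusted p = 0.0244, limma). Notch signalling had 13 of 20 genes lower, FGF signalling 11 of 24, the growth factor list of the TGF-beta, IGF, PDGF and HGF families 12 of 27, the SOX family 9 of 18, the interferon response 12 of 21, and p53 and apoptosis 8 of 17. Edn3, which encodes a ligand for melanocytes, differed by -0.76 ± 0.21 and Gadd45g, a growth arrest gene, by -0.57 ± 0.11. The cell cycle genes were lower in 27 of 35 cases, with a median of 0.07 in cKO replicate 1 and of -0.23 in cKO replicate 2, and were not called (adjusted p = 0.83). Without cKO replicate 2 their median was 0.12 with a call in the other direction (adjusted p = 2.2e-04), and without cKO replicate 1 it was -0.24 with a call (adjusted p = 1.2e-06).

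Among markers of other cell types that a skin sort could hold, the keratinocyte markers had their highest median in Het replicate 2, at 0.14, against -0.07 in Het replicate 1, and Krt5, a basal keratin gene, stood at 0.97 in Het replicate 2 and at -0.27 in Het replicate 1. Melanocyte markers likewise had a median of 0.12 in Het replicate 2 and of -0.06 in Het replicate 1. Neither list was called between the groups (adjusted p = 0.0892 and 0.979), and without Het replicate 1 both were called lower in cKO (adjusted p = 7.8e-11 and 0.00409). Among the Schwann and glial markers, 8 of 13 were lower, and Fabp7, a fatty acid binding protein gene, at -0.82 ± 0.08, and Egr2 passed adjusted over the list alone (adjusted p = 0.0130 and 0.0417, limma); the list itself was not called (adjusted p = 0.44), except under the filter on SD. Hair shaft and inner root sheath markers were lower in 13 of 23 cases, Merkel cell markers in 8 of 13, dermal sheath and smooth muscle markers in 9 of 16, endothelial markers in 8 of 15, immune markers in 8 of 20, adipocyte markers in 6 of 11 and skeletal muscle markers in 8 of 16, none of them called (adjusted p = 0.979 for each). The erythroid list held 2 measured genes and was not tested.

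Of the sex-linked genes, Xist, the RNA that silences the X chromosome in female cells, stood at -4.08 and -0.85 in the Het arrays and at 0.85 and 1.23 in the cKO arrays, a difference of 3.51 ± 1.23 that did not pass (adjusted p = 0.937 over all genes, limma) and was 1.9 without Het replicate 1. The Y-linked genes Eif2s3y, Kdm5d and Uty were lower in both cKO arrays, with differences of -1.81 ± 0.16, -0.75 ± 0.14 and -0.59 ± 0.14, and all 3 passed adjusted over the list alone (adjusted p = 0.00311, 0.0214 and 0.0312, limma). Usp9y, the other Y-linked gene measured, differed by 0.01. The list was called lower (camera, adjusted p = 0.0353; adjusted p = 0.853 with an estimated correlation), with a median of -0.59 and a mean of 0.07 that differ in sign because Xist moves against the Y-linked genes. The call was lost without Het replicate 2 (adjusted p = 0.0896), without cKO replicate 1 (adjusted p = 0.173) and without cKO replicate 2 (adjusted p = 0.225). The shift of Xist and of 3 Y-linked genes ran with the groups, beside every gene and list described above. When the 5 genes of this list were left out, a setting chosen after the data were seen, 5 other lists were called. None of those lists holds a sex-linked gene, so their medians could not change. The setting does not adjust them for a difference in sex.

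**Figure D3:**
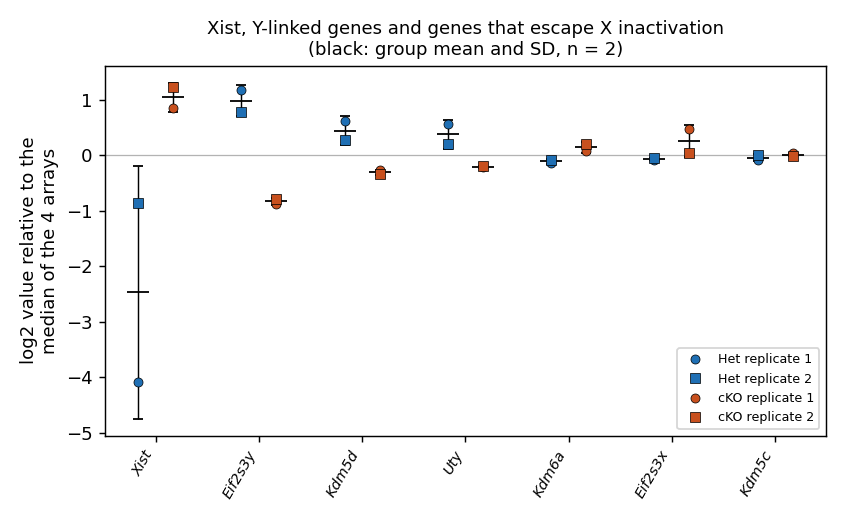
Values of Xist, 3 Y-linked genes and 3 X-linked genes that escape inactivation in each array, on a log2 scale relative to the median of the 4 arrays, with Het in blue, cKO in orange and black lines for the group mean and SD (n = 2). Xist lies at -4.08 and -0.85 in the Het arrays and at 0.85 and 1.23 in the cKO arrays, and Eif2s3y, Kdm5d and Uty lie lower in both cKO arrays.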

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

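The SD filter, the restriction to genes with 1 probe set and the list tests without sex-linked genes were chosen after the data were seen; the planned settings that need expression levels were not run. Sox2 kept its direction in every setting run, from -1.86 to -1.77 with 1 array left out, and crossed the threshold only under the SD filter, at -1.81. The number of probe sets called was 0 in every setting run except the SD filter, which called 20; that filter is built on a spread that includes the group difference and on a prior fitted to the wider probe sets, and it left 998 probe sets with an unadjusted p under 0.05. Under it 5 lists were called: the Schwann and glial markers were gained (adjusted p = 0.00573), the hypoxia list was lost (adjusted p = 0.0768) and the sex-linked list, with 4 genes left, was not tested. With the replicate number as a replicate block, 2536 probe sets had an unadjusted p under 0.05 and 0 were called; the sex-linked list was no longer called (adjusted p = 0.118), and the block changed no other call. The numbers share no stated litter or batch, and the differences between arrays 1 and 2 of both groups correlated at 0.311 across probe sets, which are not independent. A 1.5-fold threshold gave 237 separated probe sets, 60 higher and 177 lower, and the split by replicate number 319, with 77 higher and 242 lower. No list was called with an estimated correlation (0) or by fry in one direction (0). With 1 array left out, which leaves 1 residual degree of freedom and assumes that the lone array varies like the other group, the counts ran from 52 to 124 separated 2-fold probe sets, from 19 to 84 lower and from 20 to 40 higher (33 higher and 19 lower without cKO replicate 2), from 1178 to 2464 probe sets with an unadjusted p under 0.05, and from 2 to 10 lists called; fewer arrays separate more often by chance, and no other cause was tested. Against its value with all 4 arrays, the median of 3 lists turned with a call on one side, for causes that were not tested. It ran from -0.0601 (without Het replicate 1) to 0.0230 for the SOX family, from -0.344 to 0.0144 (without cKO replicate 1) for the immediate early genes and from -0.236 to 0.118 (without cKO replicate 2) for the cell cycle genes. Of 128 named genes 30 changed sign in 1 or more of these settings, as did 25 of 31 lists. Of these, 4 more turned between settings with a call in 1 of them: the keratinocyte markers were called at -0.193, the melanocyte markers at -0.121 and the hair shaft markers at -0.0212 without Het replicate 1 and stood at 0.0344, 0.0737 and 0.0565 without Het replicate 2, and FGF signalling was called at 0.0549 without cKO replicate 1 and stood at -0.0131 without cKO replicate 2. Signal over background cannot be read from centred values.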

Other observations

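The gene families and single genes in these first paragraphs were chosen after the data were seen. Genes for cytosolic ribosomal proteins were lower in cKO in 50 of 54 cases, with a median log2 difference of -0.22, and stayed lower after median centring (-0.22) and with any 1 array left out (-0.28 to -0.16). Genes for subunits of the respiratory chain, taken as 1 family with those of the ATP synthase, were lower in 60 of 76 cases. Their median was -0.15, and between -0.25 and -0.05 with 1 array left out. Camera called both families with the preset correlation (adjusted p = 9.6e-19 and 5.9e-09, limma), and neither with an estimated correlation (p = 0.115 and 0.239). Both families were lower in arrays 2 than in arrays 1 as well, in 45 of 54 and 61 of 76 cases, with medians of -0.10 and -0.18. Camera called them there too with the preset correlation (adjusted p = 8.8e-04 and 1.4e-06), and not with an estimated correlation (p = 0.541 and 0.280). Small nucleolar RNAs, a family tested beside them, were higher in cKO in 31 of 51 cases, with a median of 0.04. They were not called (camera with the preset correlation, adjusted p = 0.0524). Ribosomal protein genes have many processed copies, so their probe sets can measure more than 1 transcript.

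Meg3 and Rian, maternally expressed noncoding RNAs of the imprinted region next to Dlk1, were lower in both cKO arrays, with differences of -0.99 ± 0.05 and -0.98 ± 0.32 (SE, n = 2 arrays per group), and the paternally expressed Dlk1 had a difference of -0.21 ± 0.04. Rian stood at 0.26 in Het replicate 1 and at 1.11 in Het replicate 2, so its difference leans on the latter. Some genes that were higher in cKO had arrays close together within each group: Cxcl14, a chemokine gene, at 0.76 ± 0.06, Thbd, the thrombomodulin gene, at 0.71 ± 0.05, Dio2, which encodes a thyroid hormone activating deiodinase, at 0.81 ± 0.09, and Gpm6a, a neuronal membrane glycoprotein gene, at 0.89 ± 0.11. None of these passed over all genes; the adjusted p from limma was 0.777 for Meg3 and 0.885 for Cxcl14.

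The tests on the order of the arrays and on the genes next to Sox2 were also chosen after the results were seen, and those on Sox2, on male animals and on flanking DNA were revised after their first values were seen. The test on escape genes was set after Xist was seen and before the values of these genes were. Xist was higher in cKO by 3.51 ± 1.23 while Eif2s3y, Kdm5d and Uty were lower. A candidate explanation is a different share of male and female animals behind the Het and cKO samples. It predicts that Kdm5c, Kdm6a and Eif2s3x, which escape X inactivation, are higher in both cKO arrays, and 2 of the 3 were. Kdm6a was at 0.25 ± 0.07 and Eif2s3x at 0.32 ± 0.16, with Kdm5c at 0.05 ± 0.05 and overlapping groups. Eif2s3x stood at 0.47 in cKO replicate 1 and at 0.05 in cKO replicate 2, against -0.08 and -0.05 in the Het arrays. Ddx3x, seen earlier and left out of the test, was at 0.26 ± 0.12, with -0.02 and -0.31 in Het replicates 1 and 2. The explanation stays open, because its prediction was not met in full: Kdm5c did not separate. Xist and 3 Y-linked genes moved in the directions it gives, while the Y-linked Usp9y did not. A difference in sex would be confounded with the groups. An effect of Sox2 loss on these genes, or on any other gene described here, could therefore not be tested apart from sex.

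Of 105 genes at least 1.5-fold lower in cKO with separated groups, 70 also had array 1 above array 2 in both groups, or 66.7%. Exchangeable replicates give 25%, which assumes that the arrays of a group vary equally. The SD of the values was 0.138 and 0.107 in Het replicates 1 and 2, and 0.112 and 0.158 in cKO replicates 1 and 2. Choosing large differences favours genes in which the wider array of each group lies outermost, so 25% is not a firm baseline here. Of 24 higher genes, 9 had the mirrored order. A graded Sox2 transcript stays open. The step tested was array 1 minus array 2, kept with its sign and averaged over both groups, so opposite steps cancel. As a share of the group difference it was 0.0452 for Sox2. Over 101 other lower genes of any order this share had a median of 0.43 and a lower quartile of 0.175. Against a noise of 0.182 Sox2 thus lay clear of the median and not of the lower quartile. A share of male animals stays open too: the share found between the cKO arrays had a median of 0.412 over these genes, above the highest value of the 3 Y-linked genes, 0.0916, and a lower quartile of 0.0824, below it. An offset between arrays 1 and arrays 2 that both groups share may contribute, as the differences between arrays of a group correlated at 0.296 across genes outside the pattern, which are not independent replicates. What made the arrays differ, and how much of the group difference Sox2 loss accounts for, stays open.

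Genes next to Sox2 could differ through DNA flanking the targeted allele. The 20 nearest measured genes had a median absolute difference of 0.075, against a median of 0.0485 over 19505 such windows. This lay at percentile 87.9, above the median window and under the bound of 0.0895 at percentile 95, so a flanking effect stays open and single genes were not tested.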
